A study of Mus musculus with 4 samples.

How the data were processed

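RNA sequencing libraries were made from 4 samples of mouse embryonic stem cell-derived cardiac progenitor cells, 2 in DMSO and 2 in cucurbitacin I, with a TruSeq kit from total RNA, per the labels' protocols. The tools named in the submitters' processing notes are STAR 2.3.0e and HTSeq 0.6.0 with genome build mm10. The annotation release and whether counting used the strand are not given in the sources used here. The authors deposited 1 table with whole-number counts per gene and library, per the file headers. It also holds a normalized signal per library, deposited by the authors, which equals the count divided by 1 size factor per library (1.1675 and 1.0541 for DMSO, 0.9488 and 0.8632 for cucurbitacin I). The authors' log2 fold change, its standard error and test statistic (each a score without a fixed range), and the p-value and adjusted p-value of their comparison are deposited as well, and DESeq2's standard column names appear there per the file headers. The direction of the authors' log2 fold change was read from the counts.

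The table had 43374 lines, of which 4195 repeated a gene for a further human ortholog and were left out, leaving 39179 gene identifiers. Of the symbols, 27 were stored as dates and were restored from the gene identifier. A count was present in any library for 24380 identifiers. Coordinates are those of the deposited table on mm10; 37693 identifiers were in GENCODE M21, and 33769 had both ends within 1000 bp of it. Strand, exonic length and GC content came from GENCODE M21.

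Groups were taken from the sample titles. The counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10), TMM factors (1.107 and 1.063 for DMSO, 0.912 and 0.932 for cucurbitacin I), glmQLFit and a 2-sided glmQLFTest of cucurbitacin I against DMSO, with Benjamini-Hochberg adjustment over the 16722 genes tested and a threshold of 0.05. The standard error is the absolute log2 fold change divided by the square root of the F statistic. CPM values are scaled by TMM. The fit left 2 residual degrees of freedom, 3.5 prior ones and a common biological coefficient of variation of 15.7%, and the median standard error of a log2 fold change was 0.17. Replicate libraries correlated at 0.992 (DMSO) and 0.9915 (cucurbitacin I) across genes on the log2 CPM scale, and libraries of different groups at 0.948 to 0.9597. The chi-square per degree of freedom between replicates was 24.35 and 33.85, so no library was a second deposit of another.

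A total of 36 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 36 lists. With an estimated correlation, 0 of the 28 lists that passed kept their call. fry, which asks whether a list's genes move one way on balance, passed 24. Lists share members, for example 7 genes between smooth muscle and the actin list. The named genes are the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM, groups that did not overlap and a symbol that is not a clone or predicted name. To these were added up to 4 members past the threshold of each list (up to 3 in its more frequent direction and up to 1 in the other, by adjusted p) and 26 genes named whatever their result. Rgs5, Cspg4, Plek, Csf1r, Lcp1, Wt1 and Tbx18 fall outside the rule and were chosen after their values were seen. The same holds for the genes of the groups that open the closing observations. Of the 159 named genes tested, 147 passed; a few of them are not reported here. Genes with 3 or fewer counts in a library are given as the ratio of scaled group counts with an exact 95% binomial interval, and a group at 0 is set to 3 counts over the group. Named genes are said to overlap another gene where that gene holds at least 10% as many counts.

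The alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios factors, library totals alone, no filter, a mean of at least 50 counts, the 20 most abundant genes left out, a replicate block, each library left out, a threshold of 0.01, a test against a 1.5-fold change, an estimated correlation, fry, and adjustment over each list alone. Where a library was left out, its group had 1 library, which is assumed to vary like the other group.

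The test was checked on simulated data for the comparison of cucurbitacin I with DMSO, drawn from the real means and library sizes with 200 changed genes. Of the 16424 genes that passed the filter there, it recovered 14.9% of those changed 1.5-fold, 61.2% of those changed 2-fold and 87.9% of those changed 4-fold. Over 20 such draws from 16722 genes, 14.7% of calls were false (6.9% to 22.9% per draw) when each gene had its own estimated dispersion, above the nominal 5%. With dispersions on the fitted trend 5.5% were false, and 4.9% of unchanged genes had an unadjusted p below 0.05 in both. With 5577 changed genes in place of 200, 2.8% of calls were false and 44.4%, 77.6% and 97.9% of those changed 1.5-fold, 2-fold and 4-fold were recovered. In a separate draw only 30 genes were changed, all raised 2-fold. With a preset correlation, 4 of 100 unchanged lists of 30 genes had an unadjusted p below 0.05 there. The genes were drawn independently in that draw, and far fewer changed than were called in the data. It does not show how often lists of correlated genes, or lists amid many changed genes, would be called falsely. In the data the estimated correlation ran from -0.103 for nuclear noncoding RNAs to 0.947 for mitochondrially encoded transcripts. A list of 30 genes raised 2-fold had an adjusted p of 1.3e-29 with the preset correlation and an adjusted p of 0.57 with an estimated correlation, so the latter had little power at this sample size.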

Results

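RNA was sequenced from cardiac progenitor cells that had been derived from a mouse embryonic stem cell line with inducible Gata6, a transcription factor gene of heart and endoderm development. The cells received either the solvent DMSO (0.1% of the medium) or cucurbitacin I hydrate at 10 µM, a hit from a compound screen, for 2 days. Cucurbitacin I is a plant triterpenoid known as an inhibitor of JAK2 and STAT3 signalling. Each group held 2 libraries. Total counts over genes were 27069312 and 25573785 in the DMSO libraries and 26773886 and 23759431 in the cucurbitacin I libraries. The labels differ on the harvest, since treatment began on day 6, the sample titles name day 8 and the extraction protocol names day 10. No label states that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The comparison asked which transcripts differed between compound and solvent.

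Transcripts of contractile and actin-cytoskeleton genes and of p53 target genes were higher in the cucurbitacin I libraries. Those of interferon-response genes, of cell-division genes, and of markers of endoderm, blood and endothelium were lower. Of 36 gene lists, 28 passed with a preset correlation between genes and 0 with an estimated one. Of 16722 genes tested with edgeR, 2318 were higher and 3259 lower in cucurbitacin I at an adjusted p below 0.05. The groups' CPM did not overlap in 73% of the genes tested, where chance gives 33.3%. With library totals alone as the scaling, 1059 genes were higher and 4767 lower, so the share of higher genes among the calls was 18.2% in place of 41.6%. The median log2 fold change of all genes tested was -0.24 on that scaling and -0.01 on the main one, and every change below is relative to the latter. Without DMSO replicate 1 the counts were 389 higher and 1461 lower, and without DMSO replicate 2 they were 1071 and 2063. With 2 libraries against 2, an exact permutation test of a single gene cannot give a p below 0.33, so the calls rest on the spread that edgeR shares across genes.

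**Figure D1:**
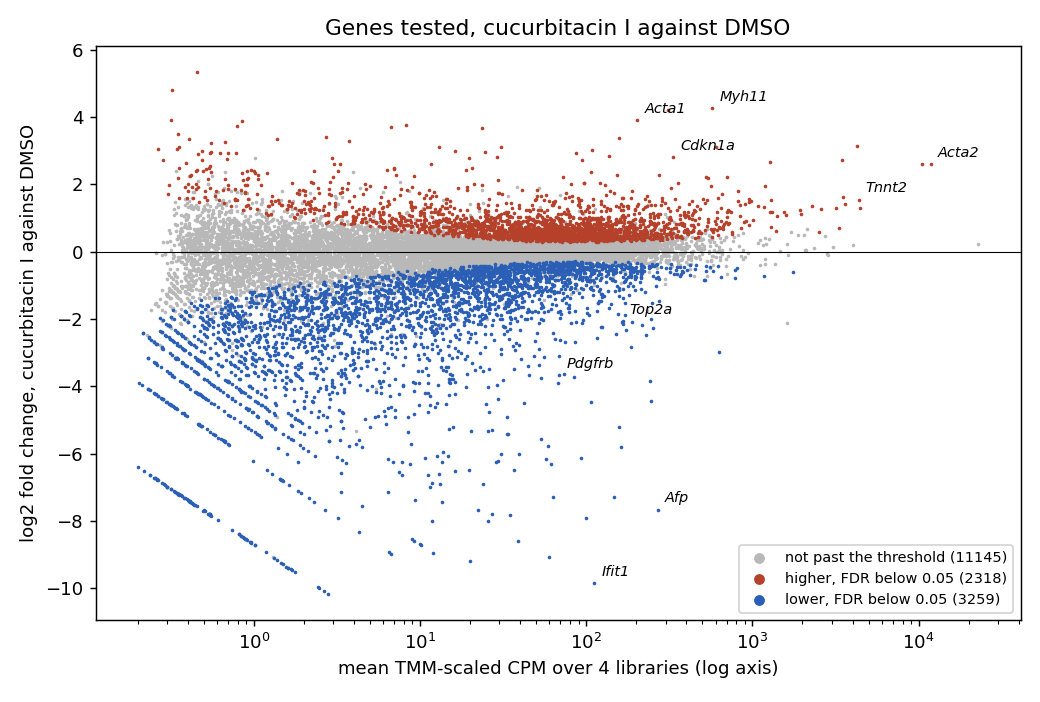
Log2 fold change in cucurbitacin I against DMSO (vertical axis) against the mean TMM-scaled CPM over the 4 libraries (horizontal log axis), 1 point per gene tested. The 2318 higher genes are red, the 3259 lower genes blue and the others grey; the diagonal stripes at the lower left are genes with very few or no counts in the cucurbitacin I libraries, whose fitted folds are not bounds.

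Smooth muscle and actin genes led the rises. Acta2, which encodes smooth muscle alpha-actin (ENSMUSG00000035783, mm10 chromosome 19, 34241090 to 34255336), went from 3330 ± 689 CPM to 20300 ± 4510 CPM (SD, n = 2), a log2 fold change of 2.61 (SE 0.31, adjusted p = 0.00506). The 10 largest rises among well-expressed genes were Myh11 (4.27), Actg2 (4.21), the skeletal actin gene Acta1 (3.91), Svop (3.76), Kcnj6 (3.71), Shroom1 (3.67), Nptx2 (3.37), Tagln (3.13), the natriuretic peptide gene Nppb (3.11) and Tpm2 (3.10) on the log2 scale. Myh11 and Actg2 varied widely within DMSO, at 56.4 ± 62.2 and 31.7 ± 32.1 CPM (SD, n = 2). Nppb did not pass without DMSO replicate 1 (adjusted p = 0.066). The 10 largest falls were in Ifit1 (-9.85), Iigp1, Oasl2 (-9.08), Serpina6, Trim30a, Irg1, Pf4, Oas1a, Rsad2 and Marco. Ifit1, an interferon-induced antiviral gene (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009), fell from 223 ± 70.2 CPM to 0.234 ± 0.075 CPM (SD, n = 2, SE of the log2 fold change 0.39, adjusted p = 0.000741). For the falls that left 3 or fewer counts in a cucurbitacin I library, the ratio of scaled counts with its 95% counting interval was 619 (211 to 3000) for Iigp1, 615 (110 to 24300) for Serpina6, 545 (151 to 4500) for Trim30a and 612 (110 to 24200) for Irg1. It was 467 (129 to 3860) for Pf4, 461 (127 to 3810) for Oas1a, 393 (207 to 860) for Rsad2 and 431 (119 to 3560) for Marco. These intervals cover counting error only.

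**Figure D2:**
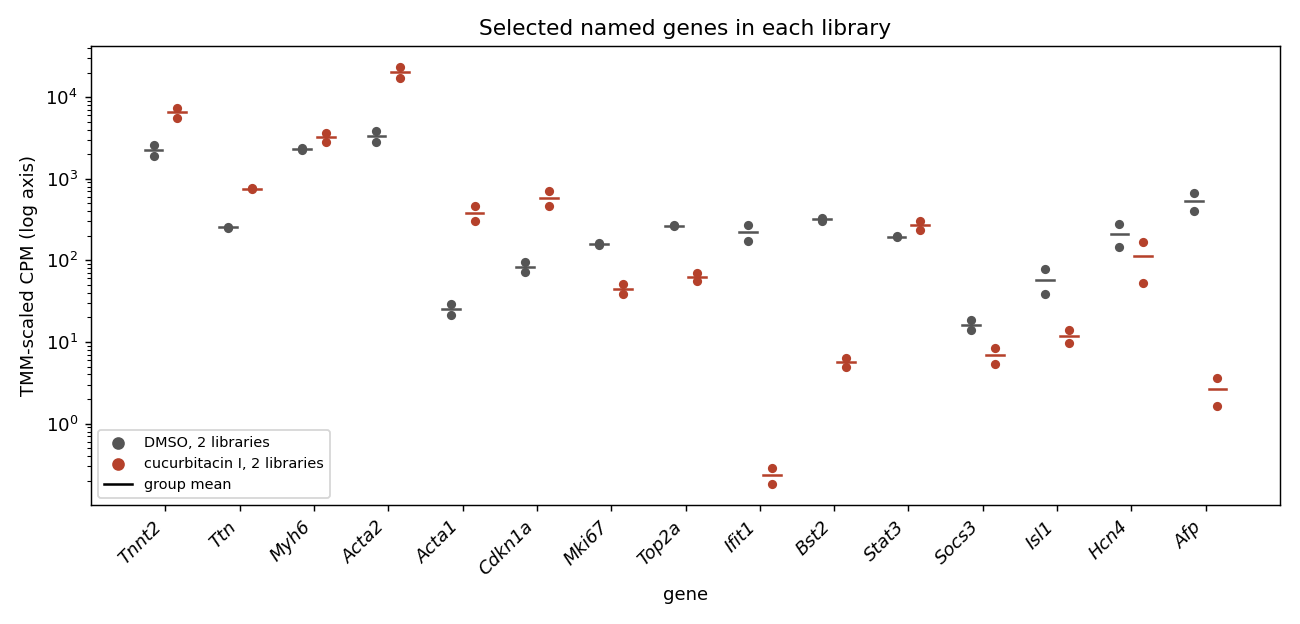
TMM-scaled CPM (log axis) of 15 named genes in the 2 DMSO libraries (grey) and the 2 cucurbitacin I libraries (red), with a line at each group mean. Acta2 averaged 3330 CPM in DMSO and 20300 CPM in cucurbitacin I, Ifit1 averaged 223 and 0.234 CPM, and the libraries of the 2 groups overlapped for Hcn4.

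Sarcomere genes rose as a group. Of 35 genes of the cardiomyocyte contractile apparatus, 23 were higher, 3 lower and 9 not past the threshold (24 and 3 adjusted over the list alone), with a median log2 fold change of 0.99 (camera adjusted p = 1.3e-06; adjusted p = 0.37 with an estimated correlation). The titin gene Ttn rose by 1.57 (SE 0.11), the Z-disc gene Ldb3 by 1.52, and the small heat shock protein gene Cryab by 1.95, while Csrp3 fell by 1.54. Cardiac troponin T, encoded by Tnnt2 (ENSMUSG00000026414, chromosome 1, 135836386 to 135852260), was at 2220 ± 487 CPM in DMSO and 6480 ± 1240 CPM in cucurbitacin I (SD, n = 2, log2 fold change 1.55, adjusted p = 0.0111). The myosin genes Myh6, Myh7, Myl2 and Myl7 did not pass: the log2 fold change was 0.47 for Myh6 (adjusted p = 0.115), 0.21 for Myh7 (0.612), -0.23 for Myl2 (0.434) and 0.49 for Myl7 (0.25). The sign of Myh7 turned with library totals (-0.03) and without cucurbitacin I replicate 1 (-0.29), as did that of Myl2 without the latter library (0.05). Myh6 passed with DESeq2 (adjusted p = 0.026), and without cucurbitacin I replicate 2 Myl2 passed (-0.56, 0.033) and so did Myh7 (0.59, at 0.05 after rounding). Genes of calcium handling and excitation went both ways. Of 30 such genes, 10 were higher and 6 lower, the same counts as adjusted over the list alone, and the list did not pass (camera adjusted p = 0.17, direction up, median 0.34, mean -0.09). It passed with DESeq2 (0.045), with library totals (0.012, median 0.12) and without DMSO replicate 2 (0.022, median 0.62). Popdc2 (1.59), Jph2 (1.44), Hrc (1.21) and the ryanodine receptor gene Ryr2 (1.14) rose, and phospholamban, Pln, fell by 2.25. Tnnt2 (adjusted p = 0.069) and Ryr2 (0.079) did not pass without DMSO replicate 1, nor did Ryr2 without cucurbitacin I replicate 2 (0.052).

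Conduction-system genes fell. Of 29 tested, 15 were lower and 1 higher (16 and 1 adjusted over the list alone), with a median of -1.17 (camera adjusted p = 0.00093; adjusted p = 0.36 with an estimated correlation; 0.075 with fry). Cntn2, a Purkinje fibre marker, fell by 3.85, the connexin gene Gja5 by 2.62, Bmp4 by 2.24 and Id2 by 2.15, whereas Scn10a rose by 1.68. The pacemaker channel gene Hcn4 was at 211 ± 94.6 CPM in DMSO and 111 ± 82.7 CPM in cucurbitacin I (SD, n = 2), and did not pass (log2 fold change -0.92, adjusted p = 0.268). It passed with the replicate number as a block (-1.07, adjusted p = 0.011) and without cucurbitacin I replicate 2 (-1.99, 0.012). Gja5 did not pass without DMSO replicate 2 (adjusted p = 0.061). Among 33 cardiac progenitor and transcription factor genes, 4 were higher and 11 lower (6 and 11 adjusted over the list alone), and the list did not pass (median -0.19, camera adjusted p = 0.51), except with DESeq2 (0.024). Hand1 (-3.38), Kdr (-3.09), Pdgfra (-2.46) and the second heart field gene Isl1 (-2.29) fell, and Mef2c rose by 0.63. Mef2c lost its call without DMSO replicate 1 (adjusted p = 0.062). Gata4 (0.22, adjusted p = 0.488), Gata6 (-0.19, 0.574), Nkx2-5 (0.25, 0.207) and Tbx5 (0.24, 0.635) did not pass, and the sign of Gata4 turned with library totals (-0.01) and without DMSO replicate 1 (-0.05). Gata6 turned without cucurbitacin I replicate 1 (0.12) and passed without cucurbitacin I replicate 2 (-0.56, adjusted p = 0.044), and Tbx5 without DMSO replicate 1 (-0.10) or cucurbitacin I replicate 2 (-0.26). A noncoding gene overlaps Gata6, and the strand used in counting is not given in the sources used here. Whether the Gata6 counts include transcripts of the inducible Gata6 of this cell line was not tested.

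**Figure D3:**
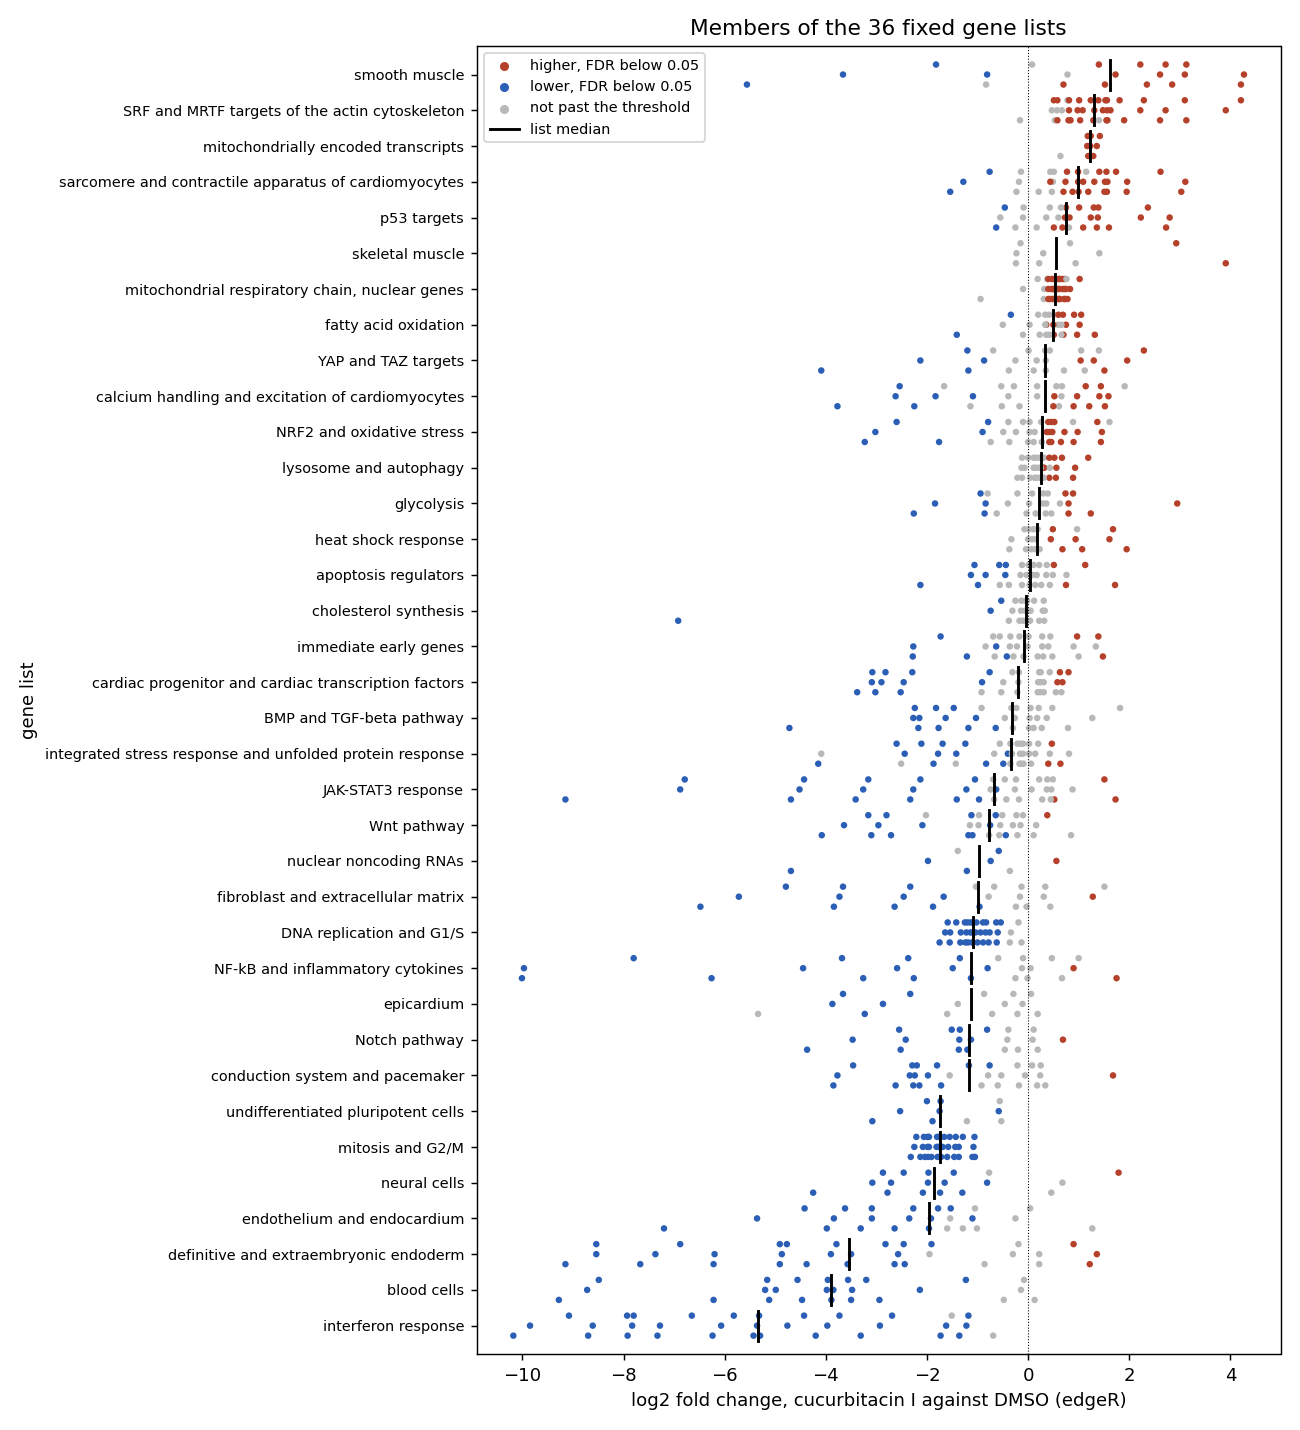
Log2 fold change in cucurbitacin I against DMSO (horizontal axis) of every tested member of the 36 gene lists (vertical axis), with list medians as black lines. Red and blue points are genes past an adjusted p of 0.05 and grey points are not; medians run from -5.34 for interferon response to 1.63 for smooth muscle.

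Targets of JAK-STAT3 signalling were lower on balance, while the call of Stat3 itself depended on the processing. Stat3 (ENSMUSG00000004040, chromosome 11, 100885098 to 100939540) was at 195 ± 2.77 CPM in DMSO and 268 ± 47.4 CPM in cucurbitacin I (SD, n = 2, log2 fold change 0.46, adjusted p = 0.0612). It passed with DESeq2 (0.037), without a filter on low counts (0.049), with a replicate block (0.048) and without cucurbitacin I replicate 2 (0.017). Of 37 list genes, 17 were lower, 3 higher and 17 not past the threshold (17 and 7 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 0.0084; adjusted p = 0.36 with an estimated correlation). Fgb (-6.88) and Icam1 (-3.26) fell and Bcl6 rose by 1.73. Fgb encodes a liver-made clotting protein, and Fgb and Fga are also members of the endoderm list, which fell. The feedback inhibitor gene Socs3 fell by 1.22 (adjusted p = 0.0232) and the kinase gene Jak2 rose by 0.52 (0.0169). Without DMSO replicate 1 neither passed (adjusted p = 0.12 and 0.1), nor did Jak2 with library totals (0.078), and the list did not pass without cucurbitacin I replicate 2 (0.064) or among genes averaging at least 50 counts (0.059). Interferon-response genes had the lowest median of the 36 lists: 32 of 34 were lower and 0 higher (33 and 0 adjusted over the list alone), with a median of -5.34, also when a gene at 0 was set to its bound (camera adjusted p = 1.7e-16; adjusted p = 0.36 with an estimated correlation). Bst2, which encodes tetherin, went from 319 ± 17.4 to 5.62 ± 1.04 CPM (SD, n = 2). Of 25 NF-kB and inflammatory cytokine genes, 14 were lower and 2 higher (15 and 3 adjusted over the list alone), with a median of -1.13 (camera adjusted p = 0.0011; adjusted p = 0.36 with an estimated correlation). Il1b had 278 counts in DMSO and 0 in cucurbitacin I, a ratio of 75.5 with the latter group set to 3 counts. The lower end of its exact 95% counting interval was 61. Tnf fell with a ratio of 85.2 (95% counting interval 23.3 to 708), and Sod2 rose by 0.90. An overlapping gene holds part of the reads around Icam1.

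Cell-division transcripts fell. All 37 mitosis and G2/M genes were lower, also adjusted over the list alone, with a median of -1.75 (camera adjusted p = 7.6e-16; adjusted p = 0.36 with an estimated correlation). Top2a fell by 2.08 (SE 0.14), Kif2c by 2.06, Kif11 by 1.99, the proliferation marker Mki67 by 1.81 and the mitotic kinase gene Cdk1 by 1.79. Of 37 replication and G1/S genes, 33 were lower and 0 higher (34 and 0 adjusted over the list alone), with a median of -1.09 (camera adjusted p = 3.2e-12; adjusted p = 0.36 with an estimated correlation). Uhrf1 (-1.75), Tyms (-1.64) and Rrm1 (-1.25) were among them. Targets of p53 rose: 17 of 29 were higher and 2 lower (18 and 2 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 7.2e-06; adjusted p = 0.36 with an estimated correlation). Cdkn1a, encoding the cyclin-dependent kinase inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090979 to 29100722), went from 83.5 ± 16.5 to 583 ± 176 CPM (SD, n = 2, log2 fold change 2.80, SE 0.26, adjusted p = 0.00297). Phlda3 (2.37), Ccng1 (2.23) and Zmat3 (1.38) rose and Ccnd1 fell by 0.63, a call lost without DMSO replicate 1, DMSO replicate 2 or cucurbitacin I replicate 1 (adjusted p = 0.14, 0.1 and 0.059). Of 31 apoptosis regulators, 4 were higher and 8 lower (5 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.78, direction up, median 0.03, mean -0.05, fry direction down). Bax rose by 0.75, while Birc5 (-2.13), Bmf (-1.06) and Bid (-0.99) fell. Bid did not pass without DMSO replicate 1 (0.058). Other genes overlap Bid and Ccnd1 and hold part of the reads there.

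Genes of the actin cytoskeleton driven by SRF and MRTF rose. Of 39, 32 were higher and 0 lower (35 and 0 adjusted over the list alone), with a median of 1.31 (camera adjusted p = 1.2e-12; adjusted p = 0.36 with an estimated correlation). Acta1 (3.91), Tpm2 (3.10) and Pdlim7 (1.90) had the smallest adjusted p. Cytoplasmic beta-actin, Actb, rose by 1.24 (SE 0.21, adjusted p = 0.0117) and Srf by 0.80 (0.00892). Actb (0.059) and Srf (0.061) did not pass without DMSO replicate 1, nor did Actb without DMSO replicate 2 (0.056). YAP and TAZ targets went both ways, with 5 of 24 higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.34, direction up, fry direction down, median 0.34), and that list passed without cucurbitacin I replicate 2 (0.0052, median 0.59). Ankrd1 (1.96), Myof (1.30) and Lats2 (1.04) rose, and each lost its call without DMSO replicate 1 (adjusted p = 0.051, 0.14 and 0.051), Myof also without DMSO replicate 2 (0.051). Lats2 overlaps Xpo4. Immediate early genes did not pass as a list, with 3 of 31 higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.78, median -0.09). Fosb (-2.28), Myc (-2.27) and Ier2 (-1.21) fell and Zfp36 rose by 0.97. Fosb did not pass without DMSO replicate 1 (0.053). Atf3 was at -0.35 (adjusted p = 0.542), with the opposite sign (0.12) without cucurbitacin I replicate 2 and a call without cucurbitacin I replicate 1 (-1.05, adjusted p = 0.045).

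Markers of other cell types moved with the treatment, mostly downward. Smooth muscle genes rose, with 13 of 20 higher and 4 lower, also adjusted over the list alone (median 1.63, camera adjusted p = 0.0087; adjusted p = 0.42 with an estimated correlation). Lmod1 (2.85) and Myl9 (2.72) rose and the mural-cell receptor gene Pdgfrb fell by 3.66. The list did not pass with the 20 most abundant genes left out (0.081) or with fry (0.23). Of 24 listed skeletal muscle genes only 10 were tested. Of these 10, 2 were higher, Acta1 and Myh3, and 0 lower, also adjusted over the list alone. The list's median was 0.56 (camera adjusted p = 0.032, or 0.36 with an estimated correlation). That list lost its call without cucurbitacin I replicate 2 (0.051), without a filter on low counts (0.094), among genes averaging at least 50 counts (0.16) and with fry (0.23), and Myh3 did so without DMSO replicate 1 (0.079). Endothelial genes fell, with 17 of 25 lower and 0 higher (20 and 0 adjusted over the list alone; median -1.96, camera adjusted p = 2.3e-07; adjusted p = 0.36 with an estimated correlation). Kdr fell by 3.09, Ramp2 fell by 3.84, and Vwf had a ratio of 42.7 (95% counting interval 18.1 to 133). Blood genes were lower in 21 of 25 and higher in 0, also adjusted over the list alone (median -3.89, camera adjusted p = 5.4e-10; adjusted p = 0.35 with an estimated correlation), among them Itga2b (-3.20) and Cd34 (-3.50), which overlaps another gene. Endoderm genes were lower in 23 of 32 and higher in 3 (25 and 3 adjusted over the list alone; median -3.54, camera adjusted p = 6.3e-07; adjusted p = 0.35 with an estimated correlation). Alpha-fetoprotein, Afp, fell by 7.67, Fgb fell by 6.88 and transthyretin, Ttr, fell by 6.22, and the basement membrane gene Col4a2 rose by 1.22, though not past the threshold without DMSO replicate 1 (0.075). Ttr and Col4a2 overlap other genes.

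Fibroblast and matrix genes were lower in 12 of 24 and higher in 1 (13 and 1 adjusted over the list alone; median -0.99, camera adjusted p = 0.0017; adjusted p = 0.36 with an estimated correlation). The elastin gene Eln (-6.48), Lum (-5.72) and Dcn (-4.79) fell, and Sparc rose by 1.28, a call lost without DMSO replicate 1 (0.11). Epicardial genes were lower in 5 of 16 and higher in 0 (6 and 0 adjusted over the list alone; median -1.13, camera adjusted p = 0.032; adjusted p = 0.43 with an estimated correlation). Aldh1a2 (-3.87), Aldh1a1 (-3.23) and Gpm6a (-2.33) fell. The other 11 members did not pass, among them Wt1 (-0.29, adjusted p = 0.769) and Tbx18 (-0.21, adjusted p = 0.85). The epicardial list lost its call without DMSO replicate 2 (0.14), without cucurbitacin I replicate 2 (0.083), with library totals (0.17) and with fry (0.082). Neural genes were lower in 14 of 18 and higher in 1, also adjusted over the list alone (median -1.86, camera adjusted p = 0.00031; adjusted p = 0.35 with an estimated correlation). Sox2 (-3.08) and Syt1 (-1.97) fell, Snap25 had a ratio of 19.6 (95% counting interval 9.29 to 49.4), and Nes rose by 1.79, not past the threshold without DMSO replicate 1 (0.063). Of 24 listed genes of undifferentiated pluripotent cells only 10 were tested. The others, among them Pou5f1, Nanog and Zfp42, had too few counts, so the list is partial. Of the 10, 7 were lower and 0 higher, also adjusted over the list alone, with Dnmt3b at -1.89 and Tfcp2l1 at -1.75. The list's median was -1.74 (camera adjusted p = 0.00068, or 0.35 with an estimated correlation).

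The Notch, Wnt and BMP lists were lower on balance. Notch pathway genes were lower in 12 of 20 and higher in 1 (13 and 1 adjusted over the list alone; median -1.17, camera adjusted p = 0.0011; adjusted p = 0.35 with an estimated correlation). Heyl (-2.42), Notch1 (-1.37) and Notch3 (-0.81) fell and Notch2 rose by 0.69. Wnt pathway genes were lower in 14 of 31 and higher in 1, also adjusted over the list alone (median -0.77, camera adjusted p = 0.00015; adjusted p = 0.35 with an estimated correlation). The Wnt antagonist gene Dkk1 (-3.64), Rnf43 (-2.96) and Sfrp2 (-2.80) fell and Fzd4 rose by 0.38. BMP and TGF-beta genes were lower in 12 of 30 and higher in 0 (13 and 4 adjusted over the list alone; median -0.31, camera adjusted p = 0.031; adjusted p = 0.36 with an estimated correlation). Msx1 (-4.72), Id2 (-2.15) and Id3 (-1.77) fell. That list did not pass without cucurbitacin I replicate 2 (0.22) or with library totals (0.082). Without DMSO replicate 1, DMSO replicate 2 or cucurbitacin I replicate 1, Fzd4 did not pass (adjusted p = 0.16, 0.11 and 0.1), nor with library totals (0.29), nor did Notch2 without either DMSO replicate (0.096 and 0.074). Other genes overlap Notch1 and Sfrp2.

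Mitochondrial energy genes rose. Nuclear genes of the respiratory chain were higher in 33 of 42 and lower in 0 (36 and 0 adjusted over the list alone; median 0.54, camera adjusted p = 3.3e-10; adjusted p = 0.42 with an estimated correlation). Ndufa5 rose by 1.02, Uqcrq by 0.72 and Cox5a, which overlaps another gene, by 0.83. Mitochondrially encoded transcripts were higher in 8 of 9 and lower in 0, also adjusted over the list alone (median 1.23, camera adjusted p = 0.00032; adjusted p = 0.42 with an estimated correlation; 0.075 with fry). mt-Nd2 rose by 1.42, mt-Cytb by 1.36 and mt-Nd4 by 1.18, with mt-Cytb not past the threshold without DMSO replicate 1 (0.057). They took 0.53% and 0.77% of all counts in DMSO and 1.19% and 1.5% in cucurbitacin I, and 6 of the 13 mitochondrial protein genes had a mean of 1 count or fewer, so the list is partial. Fatty acid oxidation genes were higher in 12 of 28 and lower in 2 (14 and 3 adjusted over the list alone; median 0.50, camera adjusted p = 0.00032; adjusted p = 0.42 with an estimated correlation; 0.075 with fry). Pdk4 (1.05), Cpt1a (1.02) and Etfdh (0.91) rose and Esrrg fell by 1.41. Glycolysis genes did not pass as a list, with 6 of 26 higher and 5 lower (8 and 7 adjusted over the list alone; median 0.22, camera adjusted p = 0.24), but passed with DESeq2 (0.045) and with fry (0.025). Car9 (2.95), Gpi1 (0.89) and Aldoa (0.80) rose and Pfkl fell by 0.86. Cholesterol synthesis genes did not pass, with 0 of 23 higher and 3 lower, also adjusted over the list alone (median -0.05, camera adjusted p = 0.47; 0.021 with fry). Acat2 (-0.74) and Mvd (-0.53) fell. Esrrg (0.053), Aldoa (0.068), Gpi1 (0.051) and Mvd (0.058) did not pass without DMSO replicate 1. Aldoa (0.053) and Mvd (0.092) also did not pass without DMSO replicate 2, nor Mvd without cucurbitacin I replicate 1 (0.057). Other genes overlap Car9 and Gpi1.

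Heat shock and lysosome genes rose as lists. Heat shock genes were higher in 8 of 22 and lower in 0, also adjusted over the list alone (median 0.17, camera adjusted p = 0.0043; adjusted p = 0.36 with an estimated correlation), with Hspb8 at 1.68 and Hspb1 at 1.61. NRF2 and oxidative stress genes were higher in 15 of 36 and lower in 6 (17 and 7 adjusted over the list alone; median 0.27, mean -0.01, camera adjusted p = 0.049, direction up; adjusted p = 0.36 with an estimated correlation). Srxn1 (1.46), Me1 (1.44), Gsr (0.65) and Hmox1 (0.46) rose and Tkt fell by 0.79. That list did not pass without DMSO replicate 1 (0.12), DMSO replicate 2 (0.076) or cucurbitacin I replicate 2 (0.11), without a filter on low counts (0.074), with a replicate block (0.066), or with the 20 most abundant genes left out (0.053). Lysosome and autophagy genes were higher in 11 of 33 and lower in 0, also adjusted over the list alone (median 0.25, camera adjusted p = 0.00057; adjusted p = 0.35 with an estimated correlation), among them Ctsd (1.19), Gabarapl1 (0.93) and Lamp1 (0.89). Integrated stress and unfolded protein response genes did not pass, with 3 of 38 higher and 12 lower (3 and 13 adjusted over the list alone; median -0.34, camera adjusted p = 0.062). They passed with DESeq2 (0.009), limma-voom (0.048), a replicate block (0.049), and without DMSO replicate 1 (0.038) or DMSO replicate 2 (0.0038). Phgdh (-2.44) and Vldlr (-1.87) fell, Nupr1 had a ratio of 18.9 (95% counting interval 7.16 to 71), and Atf6 rose by 0.40. Ddit3, which overlaps Mars, was at 0.02 (adjusted p = 0.941), with the opposite sign with library totals (-0.21), without DMSO replicate 2 (-0.24) and without cucurbitacin I replicate 2 (-0.07). Nuclear noncoding RNAs were lower in 5 of 8 and higher in 1 (6 and 1 adjusted over the list alone; median -0.97, camera adjusted p = 0.015; adjusted p = 0.36 with an estimated correlation). That list did not pass with DESeq2 (0.069) or without a filter on low counts (0.11). Snhg11 (-1.98) and Rian (-0.74) fell, Miat had a ratio of 27.3 (95% counting interval 10.4 to 102), and Malat1 rose by 0.56. Without DMSO replicate 1, Hmox1 (0.092), Tkt (0.051), Ctsd (0.075), Lamp1 (0.074), Atf6 (0.13), Malat1 (0.12) and Snhg11 (0.052) did not pass. Hmox1 (0.12) and Atf6 (0.096) also did not pass without DMSO replicate 2, Hmox1 without cucurbitacin I replicate 2 (0.069) and Atf6 without cucurbitacin I replicate 1 (0.067). With library totals Hmox1 (0.21), Atf6 (0.22) and Malat1 (0.078) did not pass.

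The authors' deposited table gives its own comparison of the same libraries. Of 19592 gene identifiers with an adjusted p in the authors' deposited table, 7527 were below 0.05, with 3321 higher and 4206 lower in cucurbitacin I. Of these, 2317 higher and 3257 lower genes were also called by edgeR in the same direction, and 0 were called in opposite directions. The authors' deposited table held 1953 calls that edgeR did not make, and edgeR made 3 that it did not hold.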

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

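All alternatives here were planned before the data were examined. None of the 147 named genes past the threshold changed sign under any alternative run, and of their 1752 values under alternatives 1699 kept direction and threshold; 33 genes lost the call in at least 1 of the 4 fits without a library, 32 of them without DMSO replicate 1. Leaving out 1 library gave 389 to 2109 higher genes, 1461 to 3001 lower genes and 24 to 28 lists, with fewer samples in each fit. Library totals gave 1059 higher genes, which follows from the shift of all fold changes by the scaling. A threshold of 0.01 gave 492 higher and 1262 lower genes, and a test against 1.5-fold gave 375 and 1666, both stricter by construction. An estimated correlation left 0 lists past the threshold (28 in the main test, 24 with fry, 31 with DESeq2). DESeq2 called 2247 higher and 3128 lower genes. The titles number the replicates alike in both groups, but no label says what a number shares; the deviations of same-numbered libraries correlated at 0.24 across genes, and a replicate block gave 2660 higher and 3707 lower genes and 28 lists.

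The genes whose sign turned and the lists whose direction turned were not past the threshold in the main test, and the cause was not tested. With library totals the log2 fold change was -0.21 for Ddit3, -0.01 for Gata4 and -0.03 for Myh7, and camera's direction turned for the immediate early list, whose median stayed below 0 (-0.33). With a mean of at least 50 counts Ddit3 was at -0.004 and the apoptosis list, whose direction turned, had a median of -0.002. Without DMSO replicate 1 Gata4 was at -0.05 and Tbx5 at -0.10; without DMSO replicate 2 Ddit3 was at -0.24. Without cucurbitacin I replicate 1 Gata6 was at 0.12, Myh7 at -0.29 and Myl2 at 0.05. Without cucurbitacin I replicate 2 Atf3 was at 0.12, Ddit3 at -0.07 and Tbx5 at -0.26, and the immediate early list, whose direction turned, had a median of 0.12; with DESeq2 camera's direction turned while that list's median was -0.13. With fry the direction turned for the apoptosis list (median 0.03) and the YAP and TAZ list (median 0.34). Over the fits without a library the values ran from -1.05 for Atf3 without cucurbitacin I replicate 1, to 0.36 for Ddit3 without DMSO replicate 1, 0.55 for Gata4 and 0.69 for Tbx5 without DMSO replicate 2, and, without cucurbitacin I replicate 2, -0.56 for Gata6, 0.59 for Myh7 and -0.56 for Myl2. The immediate early list was at -0.38 without cucurbitacin I replicate 1. Depth limits genes near 0: 3 counts correspond to 0.111 to 0.126 CPM per library.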

Other observations

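The gene groups in this paragraph and the next were chosen after the values were seen, so their counts describe these libraries and are no independent test. Plasma protein genes of hepatocytes fell together: 26 of 31 were lower in cucurbitacin I and 0 higher (median log2 fold change -5.57, or -5.18 with genes at 0 set to their bound). The vitamin D-binding protein gene Gc had 1337 counts in DMSO and 4 in cucurbitacin I, a ratio of 272 (95% counting interval 106 to 1000), and albumin, Alb, had a ratio of 403 (111 to 3340). Vtn fell by 6.00 on the log2 scale. Hedgehog pathway genes were lower in 11 of 15 and higher in 1. The target gene Gli1 fell by 7.67 (SE 0.59) and Ptch1 by 1.79. The ligand gene Shh had 747 counts in DMSO and 4 in cucurbitacin I, a ratio of 152 (59.2 to 560), while Gli3 did not pass (-0.36, adjusted p = 0.179).

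Cartilage matrix genes were lower in 9 of 13 and higher in 1, with Col9a1 at -7.30 and the regulator Sox9 at -2.43. Among imprinted genes, 13 of 22 were lower and 1 higher. Dlk1 (-2.97) and Nnat (-2.82) fell, whereas Igf2, among the most abundant transcripts in every library, was at 0.24 (adjusted p = 0.555). Splicing factor genes of the Srsf and Hnrnp families were lower in 19 of 31 and higher in 0 (median -0.46), with Srsf7 at -0.89. Of 83 cytosolic ribosomal protein genes, 19 were lower, 1 was higher and 63 did not pass; these have many near-identical pseudogene copies, so their counts are uncertain.

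For the 3 patterns below, the tests of cell type shares and of the scaling were chosen only after the results they measure were seen; those of GC content and length were written before. The fall of interferon genes was weighed against lost cells and against sequence bias. A list of 46 myeloid genes, 12 of them also in the fixed lists, had a median of 2.59 CPM in DMSO, 4.8% of the 54.1 CPM median of the 32 interferon genes that fell. The highest were Plek (23.6 CPM), Pf4 (20.2) and Csf1r (19.3), and 0 of the 46 reached 54.1 CPM, which argues against myeloid cells as the only carriers of those genes. A first list of 13, without Pf4, Marco or Irg1, gave 3.6%. Of the 46 genes, 38 fell past the threshold, but Csf1r (log2 fold change -0.14) and Lcp1 (-0.25), both among the 5 most abundant, did not; whether myeloid cells were lost stays open. The trend with GC content and exonic length explained 0.7% of the variance of the log2 fold changes. Its removal moved 26.4% of genes by more than 0.1 (-0.6 to 1.5 in all) and the interferon genes by -0.12 to 0.1, and left their median at -5.33 (quartiles -7.69 and -2.94), which argues against that trend as the whole cause. Whether the interferon transcripts may have sat in endoderm-like cells that were lost cannot be told apart from a fall within cells. The interferon median lay below that of the whole endoderm list by 1.80 (permutation p = 0.048 over genes), but that list holds genes that rose or did not pass, such as Col4a2 and Gata4, and which need not mark such cells alone. Against the hepatocyte plasma protein genes above, a group chosen after their fall was seen, the difference was 0.24 (permutation p = 0.70), or -0.16 with genes at 0 set to their bound (permutation p = 0.72), which leaves this open. A response of the cells to the compound stays open as a hypothesis.

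Markers of other cell types were lower while sarcomere genes were higher. A change of scaling moves all genes alike and would leave no gap between lists. Each gap from the sarcomere median was held against the largest gap that shuffled genes gave over all 9 fixed lists of other cell types. Genes shared between these lists were left out, so the medians differ from those given above. The gap was 2.92 for the endothelial list (permutation p = 0.044), 4.68 for endoderm and 4.86 for blood (permutation p = 0.0004 for each). A scaling cannot give a gap, so these p-values ask only whether the gaps exceed those of shuffled genes. Shuffling, as in the other permutations over genes here, treats genes as independent. The estimated correlation was 0.337 in the sarcomere list and 0.423 in the endothelial list. The p-values may therefore be too small, above all that of the endothelial list. The gaps of the other 4 lower lists, from 1.86, were within the range of shuffled genes (permutation p = 0.07 to 0.39). Whether these 4 differ from the sarcomere list beyond chance stays open, but a scaling alone would give no gap. With library totals as the scaling, the highest median of the 7 lower lists was -1.22, against -0.24 for all genes tested. A higher share of cardiomyocytes alone would lower every other type alike. The medians of the 7 lists that were lower, again without shared genes, ranged over 3 log2 units (permutation p = 0.052 over genes). These lists were picked because they had fallen, so this test decides neither way. The test had first included the smooth muscle list, which rose. Over those 8 lists the range was 5.50 (permutation p = 0.0003). A rise of smooth muscle genes of its own could give that, but it would be a change beside the share of cardiomyocytes. Of 65 sarcomere and calcium-handling genes, 33 were higher and 9 lower. A higher share alone would not lower genes that only cardiomyocytes carry. These 9 need not all be such genes, so their fall does not decide against that share. A changed mix of cells and a change within cells cannot be told apart in bulk RNA here.

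The rise of SRF-list actin genes was weighed against a higher share of smooth muscle cells. That share alone would raise genes that only smooth muscle cells carry. Of the 20 listed markers 4 fell past the threshold: Pdgfrb (-3.66), Rgs5 (-5.56), Cspg4 (-1.82) and Notch3 (-0.81). These 4 need not mark such cells alone, so their fall does not decide against that share. Of the other markers 13 rose, 7 of them outside the SRF list, so more smooth muscle cells, with or without another change, stay open. The trend with GC content and exonic length gave the SRF list's genes -0.32 to 0.11, and without it their median was 1.31 (quartiles 0.80 and 1.76). A response of SRF target genes to the compound may be followed up as a hypothesis; it was found and tested on the same libraries.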
